A study of Caenorhabditis elegans with 4 samples.

How the data were processed

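Synchronised worms were grown at 20 °C to the L3 stage, fixed with 2% formaldehyde and quenched with 100 mM Tris, per the labels' protocols. Sonicated chromatin was precipitated with an antibody against GFP, and 10% of the supernatant was kept as input. The 2 ChIP samples and 2 input samples were grouped by their titles, which also give the replicate numbers. Nothing in the labels says whether the replicates came from separate cultures, so the differences between them may be technical. The input samples were not analysed here, so no background measured in the same way can be set beside the ChIP values.

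The 3 lists were used as the authors deposited them. The combined list held 113 regions, the number also taken from the top of each replicate's list (its top set). Per the file headers they are on genome build WormBase WS220, and the method field of each line names SPP followed by IDR, a peak caller and a method that keeps the regions that replicates rank alike. The aligner, tool versions, thresholds and read depths are not given in the sources used here. Replicate regions were called per sample, and the combined list is the authors' own list over the replicates. Beyond the IDR named in the method field, how it was combined, and with which settings, is not given in the sources used here. Each region carries the score the authors deposited with it, whose scale is not given in the sources used here. For matched regions the score was used to describe the correlation between the replicates. Because many regions share the highest score, regions were ordered by the peak number in the deposited region name. In the replicate lists it runs closely, though not strictly, from the best score to the worst. In the combined list no order by score can be shown, and its numbers followed those of the replicates in part (Spearman's rho across regions 0.686 and 0.485). The widths are nearly constant in the replicate lists, and 99 of the 113 combined regions share a single width. Such a region marks a place and not the extent of binding. The ceiling on the score hides differences among the best regions.

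Regions on the mitochondrial genome (26 in replicate 1, 29 in replicate 2, 0 in the combined list) were left out of all comparisons. Regions of a pair of lists counted as shared when they overlapped by at least 50% of the shorter one. Chance overlap came from 1000 random circular rotations of one list along each of the 6 nuclear chromosomes, with a one-sided p of at least 0.000999. Chromosome lengths were not in the files, so each chromosome was taken from the first to the last region of any list, 100.2 Mb in all. Chromosome shares were tested with two-sided exact binomial tests and Benjamini-Hochberg adjustment at 0.05. Shares carry 95% Clopper-Pearson intervals, which cover counting error only and treat regions as independent. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The rotation test was tested on simulated data for the full replicate comparison. Simulated regions were placed evenly at random, without the clusters of the real lists, and each setting was run once. With 1500 planted shared regions in lists of 29974 and 18754 it estimated 1416 (permutation p = 0.005, the smallest that 200 rotations give), and with none planted it gave p = 0.836. For lists of 113 regions, the chromosome test called chromosome III in 65.5% of 1000 simulations that placed 25% of regions there. That share is close to the 24.8% observed in the combined list. In simulations without an effect it called any chromosome in 3.2%.

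Before the data were examined, the overlap, chromosome and correlation tests, the alternatives for the overlap results (overlap rule, stricter lists, list size) and for the chromosome shares, X included (a stricter list and each replicate alone), and the rule for regions to name were fixed. The rule took the 25 combined regions with the best score. Since all scores of that list are equal, the lowest peak numbers were taken instead. Chosen after seeing the data were the order by peak number, spans in place of chromosome lengths, the exclusion of mitochondrial regions and merging within 10 kb. So were rotation by 5 to 50 kb and by 1 to 5 kb, the comparison with all replicate regions and list sizes beyond the fixed ones. The alternatives for the score correlation were also chosen then. So were the chromosome shares of regions shared by both replicates, with the comparison of shared and unshared regions on X. The last were the tests of chromosome III and IV between and within the replicates, of peak numbers, of dense windows and of central positions. Tests that need genes or sequence (distance to gene starts, enrichment of fixed gene lists, annotation classes, a search for the tailless half-site and signal at nhr-67 and unc-119) were not run. The gene table at hand is of assembly WBcel235, and coordinates of different builds were not mixed. The overlap, chromosome and correlation results are therefore given by position only.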

Results

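NHR-67 is the Caenorhabditis elegans counterpart of the tailless/TLX nuclear receptors, and it is known for its part in the arrest and invasion of the anchor cell, the uterine cell that breaches the basement membranes above the developing vulva. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hermaphrodite larvae of the L3 stage, from a strain that carries an integrated, GFP- and FLAG-tagged copy of nhr-67 together with an unc-119 rescue. The labels give 2 ChIP samples, each with an input sample of unprecipitated chromatin. The values come from 3 lists of called regions on WormBase build WS220. The list of ChIP replicate 1 held 30000 regions, the list of ChIP replicate 2 held 18783 and a combined list, whose number of regions is given with the processing, was far shorter. Read depth is unknown, since the lists give no read counts. The number of regions listed per replicate does not measure it.

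Almost all regions of a replicate list had a single width, 404 bp in replicate 1 and 480 bp in replicate 2. In the combined list 99 regions (all but 14) were 590 bp wide. Merged where they overlapped, the nuclear regions covered 11.6 Mb in replicate 1, or 11.6% of the 100.2 Mb between the first and last called region of the 6 chromosomes. In replicate 2 they covered 8.46 Mb, or 8.45%, and in the combined list 0.0606 Mb. The score that the authors' caller gave each region had a ceiling. It was reached by 409 regions of replicate 1 (1.36%), at 2.91, by 1698 regions of replicate 2 (9.04%), at 3.53, and by all combined regions, at 2.82, so the score orders no combined region above another. The peak number followed the score closely, though not strictly, in both replicate lists (Spearman's rho across regions -0.999997 and -0.999578). It was used to order the regions. What orders the numbers of the combined list, where all scores are equal, is not given in the sources used here.

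The first comparison was between the replicates. The full lists shared 12.98% of the replicate 1 regions, and the share was larger only at the 500 best and smaller sizes. At the 2000 and 5000 best it was 8.75% and 8.9%. The lists ran down to scores of 0.0564 in replicate 1 and 0.338 in replicate 2. The share over the full lists therefore depends on where the lists were cut. Of 29974 nuclear regions in replicate 1, 3891 (12.98%, 95% exact interval 12.6 to 13.4) shared at least 50% of the shorter region with a region of replicate 2. Rotating the regions of replicate 2 along each chromosome 1000 times gave 2547 shared regions on average and 2703 at most, so the observed number was 1.53 times the chance value (one-sided permutation test by rotation, p = 0.000999, the smallest that 1000 rotations can give). In the other direction, 3878 of 18754 regions of replicate 2 (20.7%, 20.1 to 21.27) were shared, against 13.7% after rotation. At the top of the lists, by peak number, the excess was far larger. The score ceiling was reached by 386 nuclear regions of replicate 1 and 1670 of replicate 2. Up to the 200 best, the sets of both replicates were therefore picked among tied scores. In replicate 2 this held for the 500 and 1000 best too, which are fewer than its tied regions. Among the 50 best nuclear regions of each replicate, 20 (40%, 26.4 to 54.8) were shared, and among as many of the best as the combined list holds (the top set of a replicate) 30 were (26.5%, 18.7 to 35.7), where no more than 1 and 2 were shared in any rotation. The 1000 best gave 115 shared regions against a mean of 4.83 after rotation, and the 10000 best gave 1020 against 462. Across the 3643 region pairs matched one to one, the scores of the replicates were weakly correlated, with Spearman's rho 0.156 (bootstrap 95% interval 0.123 to 0.189) and Pearson's r 0.245. Over the 3069 pairs in which neither score was at its ceiling, rho was 0.0712. These correlations run across regions, which are not independent replicates. Since rotation alone gave 2547 shared regions on average, against 3891 observed, many of the pairs may have met by chance placement. The correlations therefore do not measure how alike the scores are at sites found in both replicates.

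**Figure D1:**
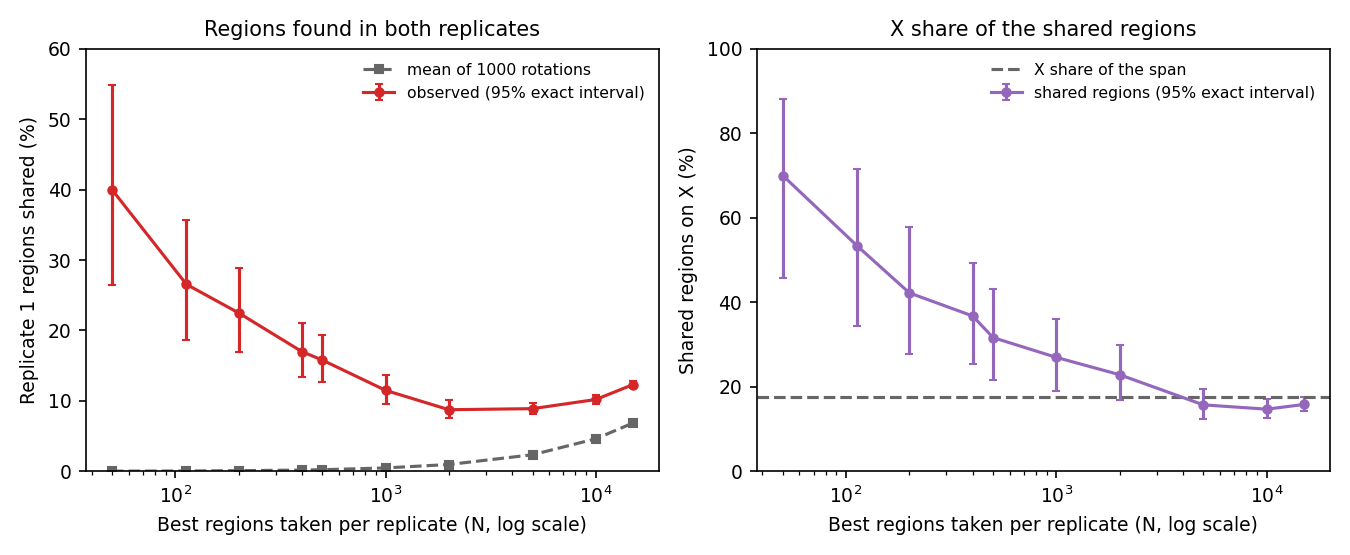
Left, the percentage of the N best nuclear regions of ChIP replicate 1 shared with the N best of replicate 2 (circles, bars 95% exact binomial intervals) and the mean of 1000 rotations (squares), against N on a log axis. Right, the percentage of those shared regions on the X chromosome (bars as on the left) with the X share of the summed span, 17.7%, as a dashed line. The shared percentage is 40 at N = 50 and 11.5 at N = 1000, and the X percentage falls from 70.0 at N = 50 to 14.7 at N = 10000. The sets are nested, so the points are not independent. Up to N = 200 the regions of both lists are tied at the score ceiling and were picked by peak number. In replicate 2 this holds up to N = 1000.

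The combined list, made from the same replicates, was then placed on the replicate lists, which describes it and is not independent evidence for its regions. Its commonest width of 590 bp and its ceiling of 2.82 are its own, so its regions are not copies of replicate regions. All combined regions were found in replicate 1 and 105 (92.9%, 95% exact interval 86.5 to 96.9) in replicate 2, hence 105 in both. By peak number the list followed replicate 1 more closely. Of the top set of replicate 1, 71 regions (62.8%, 53.2 to 71.7) were in the combined list. Of the top set of replicate 2, 48 were (42.5%, 33.2 to 52.1, two-sided Fisher's exact test p = 0.00329). The test treats the top sets as independent, though 30 regions are shared by both. Peak numbers picked these sets from 386 and 1670 nuclear regions tied at the ceiling, so unlike numbers of ties enter the comparison. Spearman's rho between the combined number and the replicate's own number was 0.686 for replicate 1 and 0.485 for replicate 2, across regions. The replicate score was at its ceiling for 94 combined regions in replicate 1, for 89 in replicate 2 and for 72 in both. The 8 combined regions without a counterpart in replicate 2 had numbers between 37 and 108. Of the 68 regions shared by the 400 best of each replicate, 14 did not overlap the combined list by a single base.

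The 25 combined regions with the lowest peak numbers were all found in both replicates, where all 25 had the highest score in replicate 1 and 24 had it in replicate 2. On X lay 14 of the 25, on III and IV 4 each, on I 2, on II 1 and on V 0. The replicate numbers given here count mitochondrial regions, which took 9 of the first 10 in replicate 1 and all 10 in replicate 2. Region 1 lay on X between 16056386 and 16056702 and carried number 13 in both replicate lists. Region 2, on III between 3867419 and 3867686, was number 16 in replicate 1 and number 14 in replicate 2. Regions 3, 4 and 5 were again on X. Region 3 spanned 11093994 to 11094294, region 4 spanned 2996959 to 2997242 and region 5 spanned 14525675 to 14526008. Their numbers were 9, 12 and 11 in replicate 1, and 28, 21 and 169 in replicate 2. Regions 6 and 9 stood side by side on X, from 11605696 to 11605928 and from 11605940 to 11606087, and both met the same region of replicate 2, number 23. Region 7 was on II between 10563412 and 10563622, and region 8 on I between 4171867 and 4172456, with numbers 25 and 38 in the replicates. Region 10 was on X between 6296239 and 6296828, with numbers 34 and 31. Of the 4 regions on IV, the lowest combined numbers were those of region 16, between 4749759 and 4750348 (numbers 66 and 42 in the replicates), and region 18, between 1094265 and 1094457 (numbers 30 and 108). Region 25, on III between 5554980 and 5555163, was number 29 in replicate 1 but 3414 in replicate 2, where its score was 2.29. All coordinates are 1-based on WS220. The genes and gene parts at these regions were not analysed here.

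**Figure D2:**
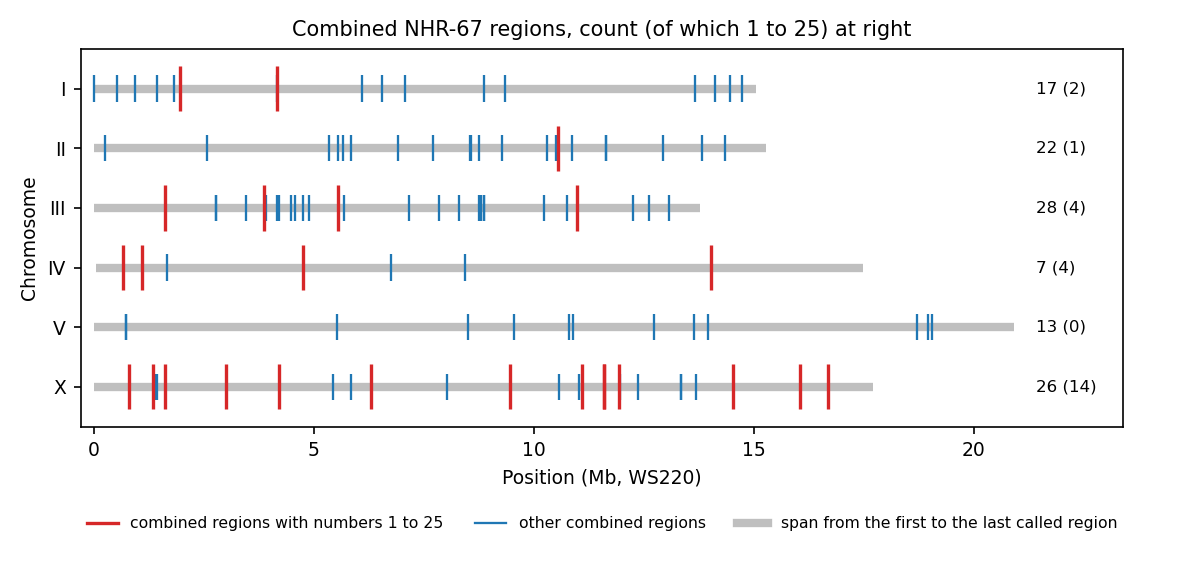
Positions of the combined regions along the 6 nuclear chromosomes (x axis in Mb, WS220). Tall red marks are the 25 regions with the lowest peak numbers, short blue marks the other regions, and grey bars run from the first to the last called region of any list. X holds 26 regions, 14 of them red, and IV holds 7.

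How the combined regions fell over the chromosomes was compared with each chromosome's share of the summed span of called regions. Chromosome III held more regions than its share and chromosomes IV and V held fewer. III had 28 regions (24.8%, 95% exact interval 17.1 to 33.8) against 13.7% of the span, a ratio of 1.80 (two-sided exact binomial test, Benjamini-Hochberg adjusted over the 6 chromosomes, p = 0.00456). IV had 7 regions (6.19%, 2.53 to 12.4) against 17.4%, a ratio of 0.356 (adjusted exact binomial p = 0.00431), and V had 13 (11.5%, 6.27 to 18.9) against 20.9% (adjusted exact binomial p = 0.0289). X with 26 regions (23.01%, 15.6 to 31.9, against 17.7%), II with 22 (19.5% against 15.2%) and I with 17 (15.04% against 15.03%) did not pass the threshold of 0.05, with adjusted exact binomial p of 0.209, 0.285 and 1.0. None of the 3 calls held in the top set of either replicate alone. For replicate 1 the shares were 22.1% on III, 9.73% on IV and 13.3% on V, with adjusted exact binomial p of 0.0816, 0.0974 and 0.0974. For replicate 2 they were 14.2%, 9.73% and 12.4%, with adjusted exact binomial p of 0.896, 0.0679 and 0.0679. Among the 1000 best regions, a size chosen after seeing the data, III passed in both replicates, at 18% and 19% (adjusted exact binomial p = 0.000488 and 1.54e-05), and V passed at 15.8% and 15.2% (adjusted exact binomial p = 0.000305 and 1.54e-05), while IV passed in neither. At the 500 best III passed in replicate 1, at 19.4%, and not in replicate 2, at 17.6% (adjusted exact binomial p = 0.00263 and 0.0964). In replicate 2 the 500 and 1000 best were picked by peak number among 1670 nuclear regions tied at the score ceiling. The full lists also had more regions on III, 15.4% in replicate 1 and 15.8% in replicate 2, and fewer on V, 19.3% and 18.3%, than the span gives. Chromosome X passed in the top set of replicate 2, at 30.1% (adjusted exact binomial p = 0.00718), and not in that of replicate 1, at 23.9% (adjusted exact binomial p = 0.128), and the difference between the replicates was not tested. At the 500 and 1000 best X passed in neither, with 20.0% and 18.1% in replicate 2 (adjusted exact binomial p = 0.213 and 0.709) and 19% and 18.6% in replicate 1 (adjusted exact binomial p = 0.535 and 0.547). X also passed among the 56 combined regions with the lowest peak numbers, of which it held 22 (39.3%, 26.5 to 53.3, adjusted exact binomial p = 0.000805), where III, at 17.9%, and IV, at 8.93%, did not. The test treats regions as independent, and 5 loci held more than 1 combined region within 1000 bp.

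**Figure D3:**
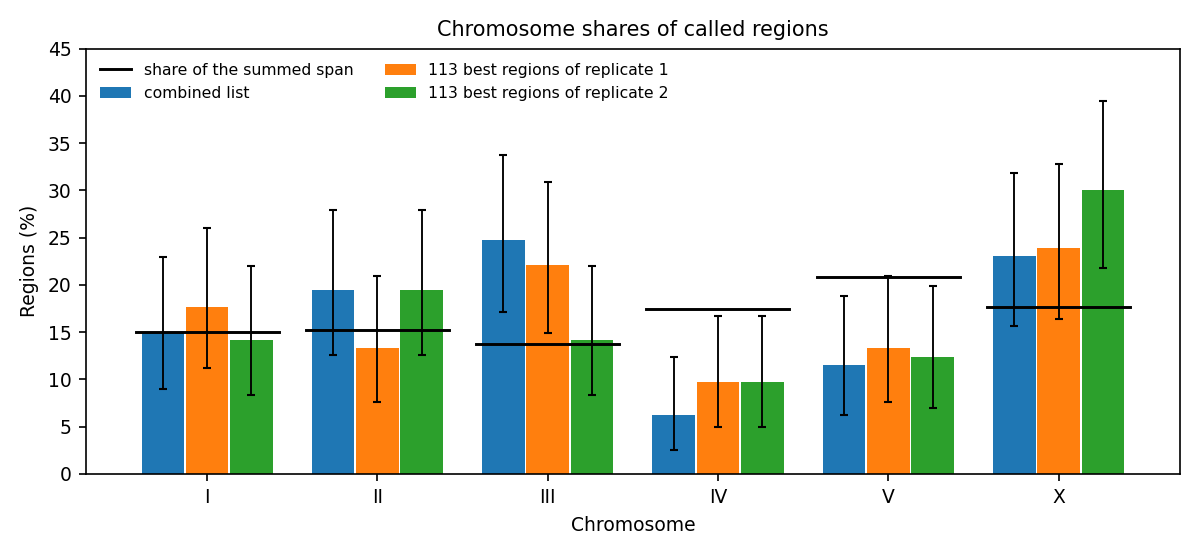
Percentage of regions on each chromosome in the combined list and in the equally many best nuclear regions of each ChIP replicate (bars from 0, with 95% exact binomial intervals), and each chromosome's share of the summed span (black lines). The combined list has 24.8% of its regions on III against a span share of 13.7%, and 6.19% on IV against 17.4%.

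Regions that both replicates ranked highest by peak number lay on X more often than its span share, and this changed with the number of regions taken. The score does not set the 50 best or the top sets apart from other regions at the ceiling. That ceiling was reached by 386 nuclear regions of replicate 1 and 1670 of replicate 2, so peak numbers alone picked these sets. In replicate 2 they also picked the 400 and 1000 best, which are fewer than its tied regions. The comparison was chosen after an X excess had been seen at several list sizes, so 6 chromosomes were tested at all 10 sizes examined, 60 tests in all. Of the 30 regions shared by the top sets of both replicates, 16 were on X (53.3%, 95% exact interval 34.3 to 71.7), 3.02 times the X share of the span (two-sided exact binomial test, adjusted over the 60 tests, p = 9.01e-05). Among the 20 shared by the 50 best, 14 were on X (70.0%, 45.7 to 88.1, adjusted exact binomial p = 1.03e-05). The X share was 36.8% of 68 regions at the 400 best (adjusted exact binomial p = 0.00104) and 26.96% of 115 at the 1000 best, where the adjusted exact binomial p was 0.0436 over the 60 tests and 0.0637 over the 6 chromosomes at that size alone. At the 2000 and 5000 best X did not pass, with 22.9% and 15.7%, and at the 10000 best it lay below its span share, at 14.7% (adjusted exact binomial p = 0.0429). Of the 60 tests 19 passed, 7 of them on X. The others, all at the smallest size or from the 2000 best on, included high shares of III and I at the 5000 best, 20.0% and 19.8% (adjusted exact binomial p = 0.00127 and 0.0258), and a low share of V there, 13.9% (adjusted exact binomial p = 0.00124). Within replicate 1, 11 of the 83 regions of the top set that were not shared lay on X (13.3%, 6.81 to 22.5), fewer than among the shared ones (two-sided Fisher's exact test p = 3.16e-05). Within replicate 2 the shares were 16 of 29 shared and 18 of 84 unshared regions (55.2% and 21.4%, Fisher's exact test p = 0.00179). Both lists enter each of these tests, so no value without either replicate can be given.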

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

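Regions on the mitochondrial genome lie outside the nuclear comparisons and were present in both replicate lists, with no input values to set beside them. Replicate 1 had 26 of them, 25 at identical coordinates from 2 to 13356, and replicate 2 had 29, all from 1 to 13394. They took 9 of the first 10 peak numbers in replicate 1 and all 10 in replicate 2. Their scores ran from 0.135 to the ceiling of 2.91 in replicate 1 and from 0.584 to the ceiling of 3.53 in replicate 2. Nearly all are repeats of a single region, so their number measures no enrichment. The combined list had 0.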

How the results depend on the processing

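The 8 alternatives for the overlap of the replicates (overlap of 1 bp, midpoints within 100 bp, stricter lists, other list sizes) kept direction and call. Each was at the smallest p the rotations allow, 0.000999. The 1000 best regions of each list enter under both overlap results as the same test, so the 8 are not all distinct. Combined regions found in both replicates, which says nothing of stability since the list was made from them, were 93.8% with an overlap of 1 bp and 76.1% with midpoints within 100 bp, against 92.9%. The alternatives for the score correlation, for merging, for the reference of all replicate regions and for the regions shared by the 1000 best were chosen after seeing the data. The correlation of replicate scores was 0.129 with an overlap of 1 bp and 0.201 with midpoints within 100 bp, against 0.156. Of the 36 chromosome alternatives, 17 kept direction and call, 12 lost the call and 2 gained one. Another 5, on I and II, turned from above to below the reference without a call. Only III, IV and V had a call to lose, and all 12 losses were theirs. I, II and X had no call in the combined list, so their unchanged alternatives do not show a call that held. Among the 56 combined regions with the lowest numbers, III at 17.9% and IV at 8.93% lost their calls, X passed at 39.3%, and I at 14.3% and II at 12.5% turned direction; fewer regions were tested there. With the best regions of 1 replicate in place of the combined list, III ranged from 14.2% to 22.1%, IV was 9.73% both times and V ranged from 12.4% to 13.3%, none past the threshold. X ranged from 23.9% to 30.1%, past it for replicate 2, I from 14.2% to 17.7% and II from 13.3% to 19.5%, with the lower value on the other side of the reference. The regions shared by the 1000 best of each replicate gave 16.5% on III, 10.4% on IV and 12.2% on V, none past the threshold. Against the chromosome shares of all replicate regions, V at 11.5% lost its call and I at 15.04% lay below. The causes were not tested. No paired analysis was possible because the input samples that share the ChIP replicate numbers were not analysed here. Settings for gene starts, gene lists, annotation classes and the half-site were not run, as no annotation of WS220 was used here. Unknown read depth and the ceiling on the score limit what can be said of the order among the best regions.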

Other observations

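All tests in this part were chosen after the results they bear on had been seen. What the peak numbers of the combined list rank is not known, since its scores are all equal. Within the combined list, the regions on X carried lower peak numbers than the others, with a median of 22 for 26 regions on X and 66 for 87 on the autosomes (two-sided permutation test of the means, 100000 resamples, p = 2e-05, the smallest they can give). The 14 combined regions narrower than 590 bp, between 148 and 334 bp wide, had a median number of 8 against 62 for the 99 full-width ones (permutation p = 2e-05). They made up 8 of the first 9 regions, and 6 of the 14 lay on X. Among full-width regions alone X still had the lower median, 30.5 against 68 (permutation p = 0.00016).

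The concentration of the best shared regions on X, 16 of 30 in the top sets but not past the threshold at the 2000 best and below the span share at the 10000 best, was set against 3 explanations. A chromosome bias of all called regions is argued against by the X share of the full lists. It was 16.6% in replicate 1 and 17.85% in replicate 2, close to the 17.7% of the span. The shared regions differed from all replicate regions (Fisher's exact test p = 6.71e-06). That test used the set in which the excess had been seen, so its p adds no independent evidence. Counting neighbours more than once is argued against by merging within 10 kb, which left 15 of 28 loci on X (exact binomial p = 1.85e-05). A preference for X among all high-ranked regions stays open: shared and unshared regions differed in replicate 1 (Fisher's exact test p = 3.16e-05) and replicate 2 (p = 0.00179), but the sets were those in which the excess had been seen, and the whole top set of replicate 2 passed for X, at 30.1%, while the 500, 1000 and 2000 best passed in neither replicate (20.0%, 18.1% and 17.6% in replicate 2 and 19%, 18.6% and 17% in replicate 1). Also open are local differences in copy number at the strongest sites, and differences in mappability or background there between X and the autosomes. The input would show these. Binding that favours X stays open too, and no biological explanation was tested.

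The high share of chromosome III in the combined list passed after merging regions within 10 kb, where III had 26 of 106 loci (adjusted exact binomial p = 0.00821), and the shares of III and IV differed from those of all replicate regions (Fisher's exact test p = 0.0127 for III and 0.00101 for IV). The Fisher tests treat the 2 groups as independent. Yet all combined regions were found in replicate 1 and 105 in replicate 2, and the reference pools both lists. Whether the shares of III and IV rest on 1 replicate was tested in 2 ways. The test run first compared the top sets of the replicates, as long as the combined list, and decided nothing, with 22.1% and 14.2% on III (Fisher's exact test p = 0.167) and 9.73% in both on IV (p = 1.0). The other, chosen after that result was known, set the best regions of replicate 2 against the rest of its list, and III was higher among the 1000, 2000 and 5000 best (Fisher's exact test p = 0.00429, 0.000571 and 0.00493) but not in the top set or among the 500 best (p = 0.795 and 0.262). An excess that replicate 1 carries alone therefore stays open for lists of the size of the combined one, as does the way that list was made, and no biological explanation was tested.

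The excess of shared regions between the full replicate lists may reflect sites bound in both samples or features of chromatin and mapping that any precipitation would share, and the lists cannot separate these; no biological explanation was tested. The density of called regions over stretches wider than the rotations accounts for part of the overlap at most. No rotation was shorter than 1 kb, so clustering finer than that was not tested. The mean rose as the rotations shortened, from 2547 for rotations along the whole chromosome. Rotations by 5 to 50 kb, which keep density over wider stretches, gave 2608 shared regions on average and 2764 at most, and rotations by 1 to 5 kb, which keep it within 25 kb, gave 2812 and 3001, against 3891 observed (one-sided permutation p = 0.000999 for each, the smallest the rotations can give).

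Counts of called regions in 25 kb windows were weakly correlated between the replicates (Spearman's rho 0.320 across 4011 windows, which are not independent replicates). Of these windows, 26 per replicate ranked among the 20 fullest with ties, and 6 were in both sets, where 0.17 would be by chance. The fullest in both was on IV between 3850001 and 3875000, with 25 regions in replicate 1 and 26 in replicate 2 and 0 combined regions. With regions placed at random, the fullest window held 19.2 on average for replicate 1 and 14.3 for replicate 2. It held as many as observed in 1 of 1000 draws for replicate 1 and in 0 for replicate 2 (one-sided permutation p = 0.002 and 0.000999, the latter the smallest the draws can give). Of the autosomal combined regions, 39.1% of 87 (95% exact interval 28.8 to 50.1) lay in the central 33.3% of their chromosome, as did 30.8% of the 26 on X (two-sided exact binomial p adjusted over 6 tests, 0.386 and 1.0). In the full lists the autosomal share was 31.6% in replicate 1, below the length share (31.02 to 32.17, adjusted exact binomial p = 2.83e-08), and 34.2% in replicate 2, where the test did not pass after adjustment (33.4 to 34.9, exact binomial p = 0.0293, adjusted 0.088). On X the shares were 32.1% and 32.7% (adjusted exact binomial p = 0.116 and 0.57). These tests treat regions as independent, though called regions gathered in dense windows, and with lists this long small departures pass. The autosomal shares of the 2 full lists lay on opposite sides of 33.3%.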
